A study of Mus musculus with 8 samples.

How the data were processed

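CD19-positive B cells had been sorted from the spleens of 4 wildtype and 4 Klf3 knockout mice with magnetic beads, 1 array per mouse. Per the labels, RNA was extracted with an acid phenol reagent, cleaned on columns, treated with DNase, labelled with biotin by in vitro transcription and hybridised to single-colour Affymetrix whole-transcript arrays. The deposited values are log2 RMA signals per probe set, which the authors made with Affymetrix Power Tools 1.8.6 per their processing notes. RMA corrects background, normalizes quantiles between arrays and summarises probes. Neither the summary level, nor the set of arrays used for it, nor a genome build was stated. The scale was checked on the values, which ran from 2.25 to 14.3 with array medians between 6.7 and 6.8 and no negative value. No 2 arrays were identical.

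Probe sets were named with the platform's annotation table. Of 35519 probe sets, 21780 carried 1 gene symbol, 1605 several and 12134 no gene; 21689 of the single-gene probe sets matched the reference gene table (GRCm38.p6) by Entrez number and 91 did not. That table served only for names and for which genes neighbour each other, since the build behind the deposited values is unknown, and no coordinates are given. Each gene was represented by the single-gene probe set with the highest mean over the 8 arrays, which gave 19935 genes, of which 998 had more than 1 such probe set. No filter on dim probe sets was applied.

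The genotypes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and an adjusted p under 0.05 as a call. Gene lists were compared with camera at its preset correlation of 0.01, with camera using a correlation estimated per list, and with fry, adjusted over the 39 of 41 lists that had at least 5 measured members. The lists covered B cell subsets, KLF family and known Klf3 and Klf1 targets, signalling and stress pathways, markers of other cell types and technical controls. For each list, members called over all genes and members adjusted over the list alone were counted. List means and principal component scores were compared between genotypes by exact permutation of the 8 arrays, and genes within 20 Mb of Klf3 with all others by Fisher's exact test. Changes are knockout minus wildtype with the SE of the limma fit, and group values are means with SD over 4 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

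The design, tests, lists and named genes were fixed before the data were examined. The named genes were Klf3, the 12 largest rises and 12 largest falls among called genes whose genotypes did not overlap, called members of the KLF and SP family, all members of the list of genes that Klf3 represses elsewhere, and up to 4 members with the smallest p from every other list. Genes chosen after their values were seen were Myof, Plac8, Cd1d1, S1pr1, Themis, S100a9, Spn, Ccr1, Cd300lf, Ackr3, Sox4, Fam114a1, Tlr1, Notch2, Cnr1, Anxa1, Anxa5, Clec4n, Rgs1, Rgs2, Rgs18, Sema7a, Sema5a, Sema4b, Plxnc1, Nrp2, Cd2, Ccl5, Il5ra, Stx11, Cd27, Nt5e, Zap70 and Cd3d.

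The alternatives were quantile normalization again, median centring, filters on dim probe sets (the median probe set, or a log2 mean of 6), the mean or the most variable of a gene's probe sets, every probe set on its own, eBayes with trend and robust, array weights, the replicate number as a block, and covariates for Xist and the T cell, erythroid and monocyte list means. Each array was left out in turn, a fold of 1.5, an adjusted p of 0.1 and complete separation of the genotypes were tried as thresholds, and genes near Klf3 were left out. Leaving out the wildtype arrays with high Xist was added after the data were seen. The calls were also counted in all 35 splits of the 8 arrays into 4 and 4.

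The procedure was tested on simulated data of 19935 genes with known changes. It called 94% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or more, and 11 of its 225 calls were false (4.89%). A shift of −0.40 in the marginal zone list was called, and 0 other lists were. The simulated genes were drawn independently of each other, whereas the estimated correlation of the real marginal zone list was 0.26. The simulation therefore does not show how often lists of correlated genes are called falsely. Arrays give no read depth, so no counting error or detection floor was computed.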

Results

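Gene expression was measured in splenic B cells of 8 FVB/NJ mice aged 10 to 12 weeks, 4 labelled wildtype and 4 labelled Klf3 knockout. The cells had been isolated with magnetic beads against CD19, a surface protein of B cells, and RNA of each mouse went onto a whole-transcript array. Klf3 encodes a zinc finger transcription factor known mainly as a repressor that recruits the corepressor CtBP. The comparison of genotypes asks which transcripts of these cells differ when the mice are labelled as lacking Klf3. Each array held 35519 probe sets with a median log2 signal between 6.7 and 6.8. Correlations between arrays, taken across probe sets and so not over independent replicates, lay between 0.986 and 0.995. The number of arrays, 4 per genotype, limited the precision.

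The array carried 1 probe set for Klf3, and its signal did not separate the genotypes. It was 9.11 ± 0.07 in wildtype and 9.18 ± 0.29 in knockout-labelled arrays (log2, SD, n = 4 each), a log2 change of 0.06 ± 0.11 (SE) with a limma adjusted p of 0.918. The labels do not say which part of the gene was removed, so this probe set checks nothing about the genotype, and every direction given here is between the arrays as they were labelled. The sexes of the mice were not given. Xist, the transcript of the inactive X chromosome, was 11.6 and 11.2 in wildtype replicates 1 and 3 and between 5.25 and 5.48 in the other 6 arrays. The Y-linked transcript Eif2s3y was 3.84 and 4.00 in those 2 wildtype arrays and between 9.94 and 10.3 in the others, so the arrays with high Xist were all in the wildtype group.

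The CD19-selected cells of knockout-labelled mice differed from wildtype in 250 of 19935 genes by limma, of which 107 were higher and 143 lower. Changes were moderate: the median size among the called genes was 0.50 on the log2 scale, 94 genes changed by at least 1.5-fold (33 higher, 61 lower) and 29 by at least 2-fold (8 higher, 21 lower). The 4 arrays of each genotype did not overlap in 1168 of all genes (5.86%, where chance gives 2.86%). An unadjusted p under 0.05 was found for 1933 genes, against 996.75 expected by chance. Other splits of the 8 arrays into 4 and 4, which mix the genotypes, gave up to 2564 such genes. The count of 1933 alone therefore does not exclude chance. On the principal component with the largest share of variance (31.2%), genotype separated the arrays with an exact permutation p of 0.0286, two-sided, the smallest that 4 against 4 can give, and without wildtype replicate 1 the exact p was 0.343.

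The 12 largest rises ran from 0.85 to 1.58 on the log2 scale. Col6a4, a collagen VI chain, was 2.99-fold higher (log2 1.58 ± 0.09 SE, limma adjusted p = 1.90e-06). Anxa2, a calcium-dependent membrane-binding annexin, was 2.82-fold higher (SE 0.11 on the log2 scale, limma adjusted p = 4.56e-05), and Vim, the intermediate filament vimentin, 2.19-fold higher (log2 1.13 ± 0.08, limma adjusted p = 2.02e-05). The adhesion molecule L1cam rose by 1.26 ± 0.12, the calcium-binding S100a6 by 1.23 ± 0.13, the phosphodiesterase Smpdl3a by 1.19 ± 0.09 and the galectin Lgals3 by 1.14 ± 0.15 on the log2 scale. Slc25a24, a mitochondrial carrier (1.03), Klf12 (0.94), Pdlim1 (0.89), the glucocorticoid-induced Tsc22d3 (0.86) and Jchain, which joins polymeric immunoglobulins (0.85), completed the 12.

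The 12 largest falls ran from −1.21 to −1.94 on the log2 scale. Ccl3, a chemokine, was 3.83-fold lower (log2 −1.94 ± 0.27, limma adjusted p = 0.00298). Tlr6, a Toll-like receptor for bacterial lipopeptides, was 3.67-fold lower (log2 −1.87 ± 0.07, limma adjusted p = 4.38e-08), the smallest p of all genes. S1pr3, a sphingosine 1-phosphate receptor, was 2.93-fold lower (log2 −1.55 ± 0.12, limma adjusted p = 5.11e-05). The C-type lectin receptors Clec4e and Clec4d changed by −1.66 and −1.36, the adhesion molecule Ceacam2 by −1.42, the cytokines Il18 and Il1f9 by −1.24 and −1.23, and the scavenger receptor Cd36 by −1.23 on the log2 scale. Rgs13, a regulator of G-protein signalling (−1.27), Tsga13 (−1.25) and I830077J02Rik (−1.21) were the others. Among the wildtype arrays, Ccl3, Clec4e, Clec4d and Il1f9 were lowest in replicate 3 (6.55, 5.92, 6.29 and 5.45). The called monocyte markers Cd14 (5.86) and Tyrobp (7.93) were lowest there too, as were the called neutrophil markers Il1b (6.32), Cxcr2 (5.16) and Csf3r (6.15). The other called neutrophil markers, S100a8 and S100a9, were lowest in replicate 2 (6.58 and 7.09, against 6.64 and 7.17 in replicate 3). Whether Ccl3, Clec4e, Clec4d and Il1f9 fell in B cells or reflect other cells in the sorts was not tested.

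**Figure D1:**
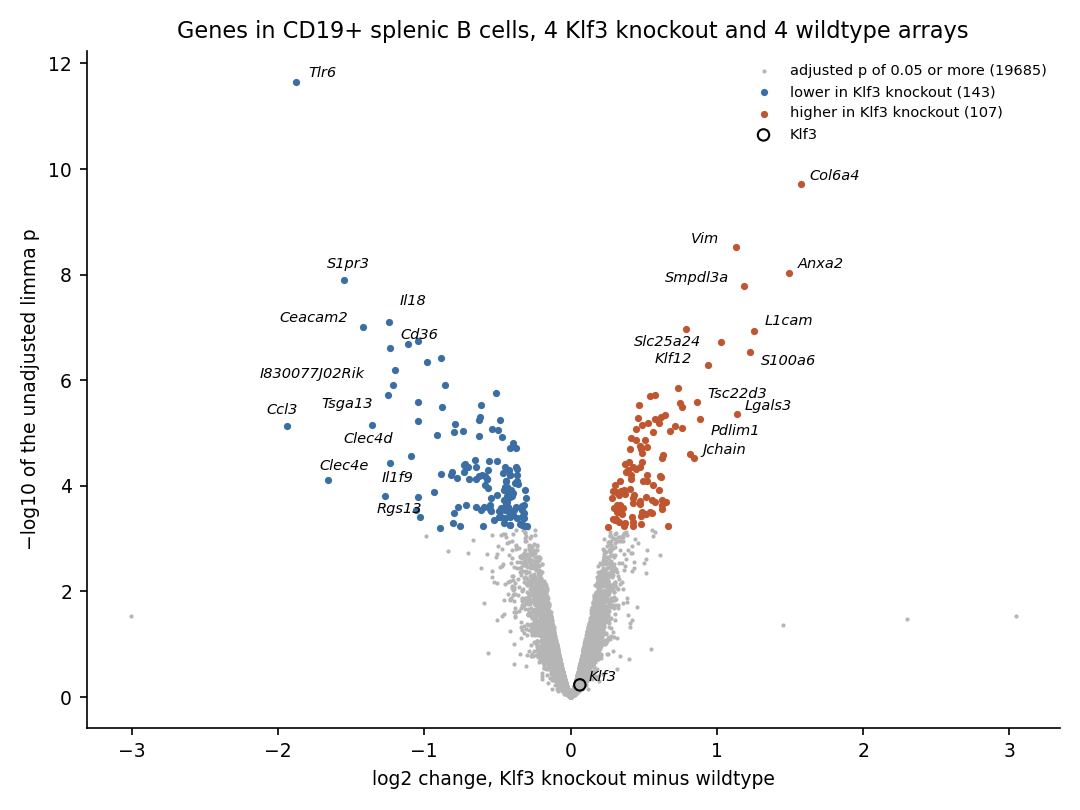
Each point is 1 of 19935 genes, with the log2 change (Klf3 knockout minus wildtype, 4 arrays each) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. Blue and orange points are the 143 lower and 107 higher genes, the 12 largest changes in each direction are named, and Klf3 (open circle) lies near 0 at 0.06.

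The count of genes depended on which arrays and covariates entered. Without the wildtype arrays with high Xist 93 genes were called, 85 of them among the 250, and without wildtype replicate 1 or knockout replicate 2 the counts were 148 and 163. With the mean of the T cell list, the erythroid list, the monocyte list or Xist as a covariate they were 10, 20, 97 and 92. The larger number of lower genes was not stable either, with 75 higher and 73 lower without wildtype replicate 1, 152 and 139 with array weights, and 124 and 125 after quantile normalization again. Of the 24 genes with the largest changes, 23 stayed called in the same direction without the wildtype arrays with high Xist, the exception being Rgs13 (−1.05 ± 0.24 against −1.27 ± 0.24, limma adjusted p = 0.125), and 7 with the T cell covariate. With that covariate, which shares 58.4% of its variance with the genotype, changes such as those of Ccl3 (−2.05 ± 0.43), S100a6 (1.28 ± 0.20), Slc25a24 (1.06 ± 0.17) and Il18 (−1.14 ± 0.18) kept their size but, with larger errors, lost their calls (limma adjusted p from 0.0625 to 0.218). By contrast Rgs13 shrank to −0.66 ± 0.31, Tsga13 to −0.76 ± 0.16, I830077J02Rik to −0.81 ± 0.17 and Cd36 to −0.86 ± 0.14, none of them called. Clec4e was −1.58 ± 0.32 without wildtype replicate 1, against −1.66 ± 0.29 (limma adjusted p = 0.0509).

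Marginal zone B cell genes were lower in the knockout-labelled mice. Marginal zone B cells are the splenic subset that faces the blood and responds early to blood-borne antigens. Of 19 measured members of this list, 11 fell, none rose and 8 did not pass the test, while 13 fell when adjusted over the list alone. Their median log2 change was −0.42 (camera adjusted p = 1.13e-24; adjusted p = 0.0578 with an estimated correlation). S1pr3, which these cells express strongly, fell by 1.55 ± 0.12, Cd36 by 1.23 ± 0.12, the ubiquitin ligase subunit Asb2 by 1.11 ± 0.11 and Zc3h12c by 0.98 ± 0.10 on the log2 scale (SE). Cr2, the complement receptor CD21, was abundant in both groups and changed by −0.42, from 12.6 ± 0.08 to 12.1 ± 0.12 (SD, n = 4 each). The other called members were Myof (−1.04), Tlr3 (−0.81), Plac8 (−0.79), Cd1d1 (−0.65), Fcrl5 (−0.43) and Mzb1 (−0.41), and S1pr1 (−0.27) and Dtx1 (−0.33) were added when adjusted over the list alone. The mean of the list was 9.23 ± 0.13 in wildtype and 8.68 ± 0.07 in knockout-labelled arrays (exact permutation p = 0.0286, two-sided, the smallest possible). Notch2, the receptor that directs B cells to this fate, changed by 0.03 and was not called. T cell markers moved the same way, with a list median of −0.20. Without the wildtype arrays with high Xist 6 members were called with a median of −0.37. With the T cell covariate 1 was called with a median of −0.29 (camera adjusted p = 2.69e-15 at the preset correlation). Errors were larger there, and most called members also changed less. They were Cd36 (−0.86 ± 0.14), Asb2 (−0.79 ± 0.13), Zc3h12c (−0.66 ± 0.12), Myof (−0.63 ± 0.14), Tlr3 (−0.38 ± 0.15), Cd1d1 (−0.33 ± 0.12), Cr2 (−0.29 ± 0.10) and Fcrl5 (−0.23 ± 0.10). S1pr3 (−1.42 ± 0.19), Plac8 (−0.74 ± 0.17) and Mzb1 (−0.40 ± 0.13) kept most of their size.

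Follicular B cell genes, of the main recirculating subset, showed small changes in the opposite direction. None of 10 measured members was called over all genes and 3 rose when adjusted over the list alone, namely Ccr7 (0.25), Klf2 (0.28) and Cd55 (0.29). The median was 0.12 (camera adjusted p = 0.0113; adjusted p = 0.248 with an estimated correlation), and without the wildtype arrays with high Xist it was 0.08 (camera adjusted p = 0.235). Transitional and immature B cell genes were lower, with 4 of 15 called and 5 when adjusted over the list alone. Vpreb3, a partner of immunoglobulin chains in early B cells, fell by 0.82 ± 0.14, the C1q receptor-like protein Cd93 by 0.61 ± 0.10, Cd24a by 0.54 ± 0.10 and the transcription factor Myb by 0.42 ± 0.07 on the log2 scale; Sox4 (−0.21) was the member called over the list alone. The median was −0.12 (camera adjusted p = 1.43e-05; adjusted p = 0.0578 with an estimated correlation), and it shrank to −0.08 without wildtype replicate 1 (3 called) and to −0.04 without the wildtype arrays with high Xist (1 called, camera adjusted p = 0.00132).

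**Figure D2:**
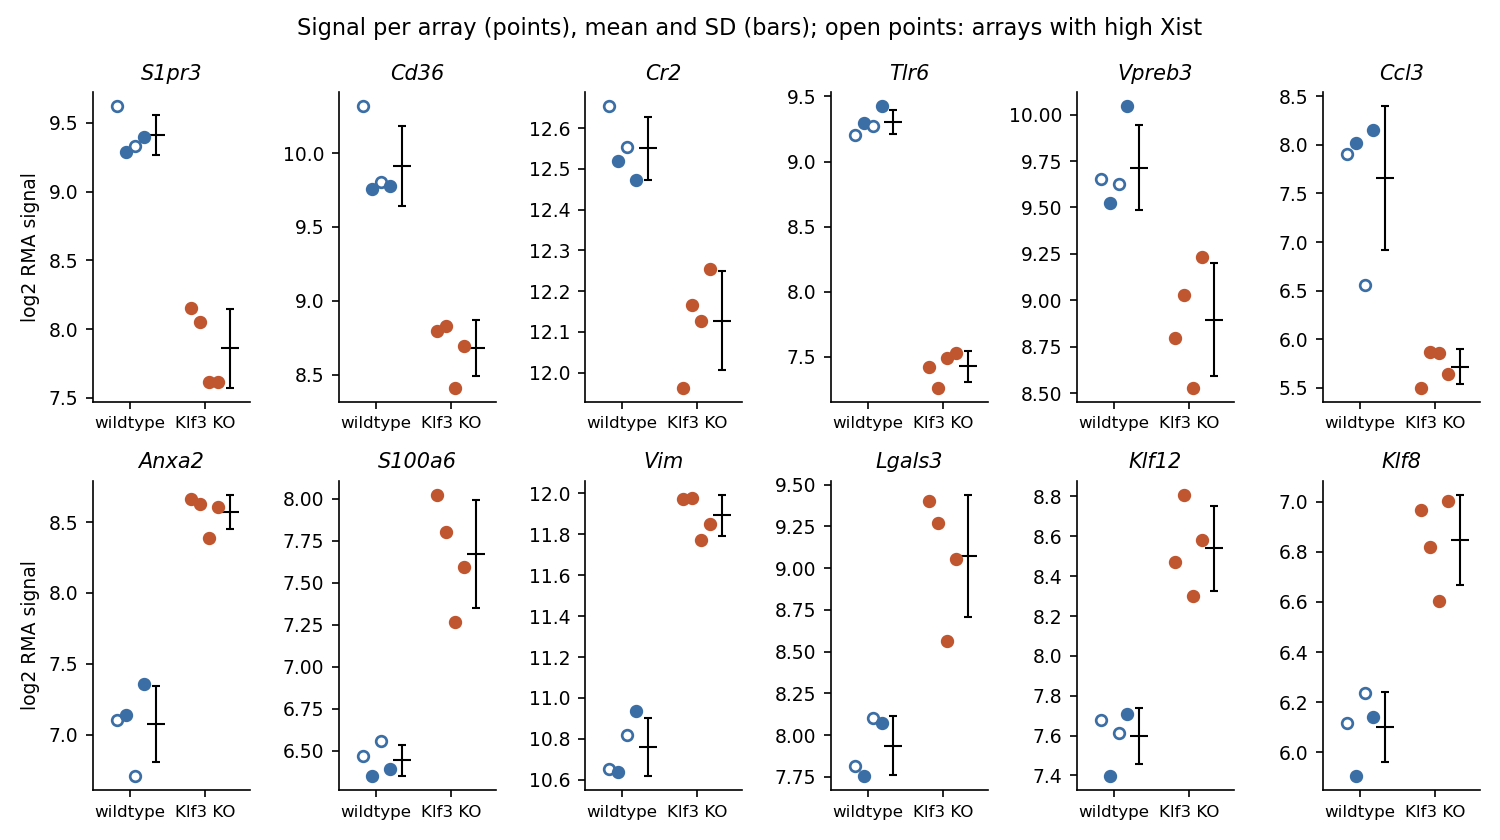
Each point is the log2 RMA signal of 1 array for the gene named above the panel, with wildtype in blue and Klf3 knockout in orange, open points for the 2 wildtype arrays with high Xist, and bars for the mean and SD of 4 arrays. The genes were picked among the called ones; S1pr3 is lower (log2 −1.55) and Vim higher (1.13) in knockout-labelled arrays, and the vertical axes start above 0 and differ between panels.

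Genes of B1 cells, the innate-like B cells of body cavities and spleen, moved in both directions. Among 16 measured members 5 rose, namely Anxa2, S100a6, the scaffold protein Ahnak (0.82), Spn, the sialoprotein CD43 (0.62), and the galectin Lgals1 (0.60). Another 3 fell, namely Ccr1 (−0.59), Fcrl5 (−0.43) and Cd300lf (−0.42). In total, 6 rose (with Zbtb32, 0.28) and 4 fell (with Il5ra, −0.51) when adjusted over the list alone. The median of the list was −0.08, its mean was 0.16, and camera gave an upward direction that did not pass (adjusted p = 0.426; adjusted p = 0.846 with an estimated correlation), while the mixed fry test, which asks for changes in either direction, passed (adjusted p = 2.82e-05). Without the wildtype arrays with high Xist the change of Ahnak was 0.79 ± 0.17, against 0.82 ± 0.13, and with fewer arrays it was not called (limma adjusted p = 0.0843). The 3 falls lost their calls there too, namely Ccr1 (−0.60 ± 0.12, limma adjusted p = 0.0613), Fcrl5 (−0.32 ± 0.08, 0.184) and Cd300lf (−0.35 ± 0.11, 0.367), and 1 of them, Fcrl5, stayed called without wildtype replicate 1. In the memory B list of 8 genes the costimulatory ligand Cd80 rose by 0.57 ± 0.08 and the chemokine receptor Ccr6 by 0.41 ± 0.07, with 4 higher (Zbtb32 and Pdcd1lg2 too, 0.28 and 0.29) and 2 lower (Cd27 and Nt5e, −0.20 and −0.15) when adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.0461; adjusted p = 0.248 with an estimated correlation), and without the wildtype arrays with high Xist it was 0.09 (camera adjusted p = 0.145) and Ccr6 was not called (0.44 ± 0.10, limma adjusted p = 0.106). In the age-associated B list of 10 genes Zeb2 (−0.64), Fas (−0.48) and Fcrl5 fell, 4 with Itgax (−0.22) when adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.248 with an estimated correlation). Of 13 germinal centre genes Rgs13 and Fas fell, with 2 higher (Pou2af1 and Stx11, 0.20 and 0.21) and 4 lower (Mybl1 and Gcsam too, −0.99 and −0.61) when adjusted over the list alone (camera adjusted p = 0.00728; adjusted p = 0.248 with an estimated correlation). The direction of the germinal centre list turned, without passing, with probe sets at or above the median probe set (camera adjusted p = 0.6645). Its median of −0.07 was −0.14 without wildtype replicate 1, where 1 member was called and Fas was not (−0.38 ± 0.08, limma adjusted p = 0.0622). None was called without knockout replicate 2, and none of this or the age-associated list without the wildtype arrays with high Xist. There the germinal centre and age-associated medians were −0.14 and −0.15, against −0.07 and −0.14 with all arrays. Zeb2 kept its size with fewer arrays (−0.64 ± 0.12, limma adjusted p = 0.0543), and Fas shrank to −0.35 ± 0.09.

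Among genes that Klf3 is known to repress in other tissues, 3 of 7 measured members rose and none fell, the same 3 when adjusted over the list alone. They were Lgals3 (1.14 ± 0.15), the related factor Klf8 (0.75 ± 0.09, limma adjusted p = 0.00185) and the integrin chain Itgb7 (0.48 ± 0.09, limma adjusted p = 0.0255). The embryonic globins Hbb-bh1 (−0.07), Hbb-y (−0.04) and Hba-x (0.06) and the secreted protein gene C1qtnf12 (−0.04) were not called. The camera adjusted p was 0.00293 with an upward direction (adjusted p = 0.218 with an estimated correlation), and Itgb7 lost its call without the wildtype arrays with high Xist (0.35 ± 0.09, limma adjusted p = 0.241) and without wildtype replicate 1 (0.39 ± 0.08, 0.0573). Across 24 measured KLF and SP family genes, Klf3 included, Klf12 (0.94 ± 0.10) and Klf8 rose, 3 with Klf2 when adjusted over the list alone (camera adjusted p = 0.0156; adjusted p = 0.248 with an estimated correlation; 0.0677 without wildtype replicate 1). Of 16 genes that Klf1 drives in red cells, Klf8 rose and Cd24a fell, with 3 higher (E2f2 and Slc4a1 too, 0.32 and 0.29) and 1 lower when adjusted over the list alone (camera adjusted p = 0.0353; adjusted p = 0.281 with an estimated correlation). Without wildtype replicate 1 that list did not pass (camera adjusted p = 0.132), and Cd24a was not called (−0.53 ± 0.12, limma adjusted p = 0.0763). The list of CtBP complex genes had 1 of 13 members called, Fhl3 (0.33), also when adjusted over the list alone (camera adjusted p = 0.361). That call was lost without wildtype replicate 1 (0.30 ± 0.07, limma adjusted p = 0.0780), without knockout replicate 2 and without the wildtype arrays with high Xist (0.28 ± 0.08, 0.293).

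Toll-like receptor and innate sensing genes were lower, with 4 of 20 measured members called and 9 when adjusted over the list alone. Besides Tlr6 these were the RNA sensor Tlr3 (−0.81 ± 0.14), Cd14 (−0.76 ± 0.17), a coreceptor for lipopolysaccharide, and Cd180 (−0.33 ± 0.07), a B cell homologue of Tlr4. The median of the list was −0.17 (camera adjusted p = 1.89e-09; adjusted p = 0.147 with an estimated correlation), and that of the monocyte and macrophage markers was −0.21. Without wildtype replicate 1, 2 members were called and the list median was −0.15. Cd14 (−0.69 ± 0.18, limma adjusted p = 0.173) and Cd180 (−0.31 ± 0.07, 0.105) then lost their calls. Leaving out the wildtype arrays with high Xist also left 2 called, with a list median of −0.17. Cd180 then kept its size (−0.33 ± 0.09, limma adjusted p = 0.239) and Tlr3 shrank (−0.56 ± 0.11, 0.0551), neither being called. Cell cycle genes had no called member, 4 lower when adjusted over the list alone (Bub1, Top2a, Bub1b and Mki67, between −0.43 and −0.26), and all 29 members below 0 with a median of −0.12 (camera adjusted p = 7.55e-08; adjusted p = 0.248 with an estimated correlation). None of the 4 was left without wildtype replicate 1, knockout replicate 2 or the wildtype arrays with high Xist, where the list medians were −0.10, −0.11 and −0.11. B cell receptor signalling genes (25 members, median −0.09, camera adjusted p = 2.10e-04) and unfolded protein response genes (20 members, median −0.14, camera adjusted p = 4.11e-04) had no called member, nor any when adjusted over the list alone (adjusted p = 0.248 with an estimated correlation for both).

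Markers of some other blood cells differed between the genotypes, while those of dendritic cells, platelets and mast cells did not pass. Of 19 T cell markers 5 fell, namely Cd3g (−1.06), Cd8a (−0.91), Cd8b1 (−0.65), Themis (−0.61) and Lat (−0.47), and 7 with Cd3d (−0.36) and Zap70 (−0.20) when adjusted over the list alone (median −0.20; camera adjusted p = 2.42e-09; adjusted p = 0.248 with an estimated correlation). Of 20 neutrophil markers 5 fell, Il1b (−1.04), Cxcr2 (−0.78), S100a8 (−0.77), S100a9 (−0.60) and Csf3r (−0.46), the same number when adjusted over the list alone (camera adjusted p = 3.90e-04). Among 23 monocyte and macrophage markers Cd14 and Tyrobp (−0.62) fell, 4 with Vcam1 (−0.70) and C1qb (−0.40) when adjusted over the list alone (camera adjusted p = 3.57e-07), and among 15 natural killer cell markers Nkg7 (−0.56) and Prf1 (−0.41) fell, also when adjusted over the list alone (camera adjusted p = 5.65e-04). With an estimated correlation the adjusted p was 0.248 for these 3 lists. With the T cell covariate the direction of the natural killer list turned, and with its own mean as a covariate that of the monocyte list, neither passing (camera adjusted p of 0.6585 and 0.7476). Over the 4 lists 14 members were called lower, 7 without wildtype replicate 1 and 4 without knockout replicate 2. The count was 6 without the wildtype arrays with high Xist and 0 with the T cell covariate. Fewer calls did not mean smaller changes throughout. With all arrays the T cell, neutrophil, monocyte and natural killer medians were −0.20, −0.07, −0.21 and −0.03. Without knockout replicate 2 they were −0.16, −0.08, −0.28 and −0.04. Without the wildtype arrays with high Xist Il1b (−1.315), Cxcr2 (−0.996), Cd14 (−0.98) and Csf3r (−0.56) changed more than with all arrays. Cd3g (−0.65), Cd8a (−0.67), Cd8b1, Themis, Lat, Nkg7, Prf1, S100a8, S100a9 and Tyrobp changed less there. Erythroid markers had an upward direction (18 members, median 0.08, camera adjusted p = 0.00902; adjusted p = 0.248 with an estimated correlation), yet the only called member, also over the list alone, was the iron carrier Slc25a37 (−0.34). Without wildtype replicate 1 the erythroid list did not pass (camera adjusted p = 0.0749), and Slc25a37 was not called there (−0.35 ± 0.08, limma adjusted p = 0.114) or without the wildtype arrays with high Xist (−0.42 ± 0.09, 0.109).

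**Figure D3:**
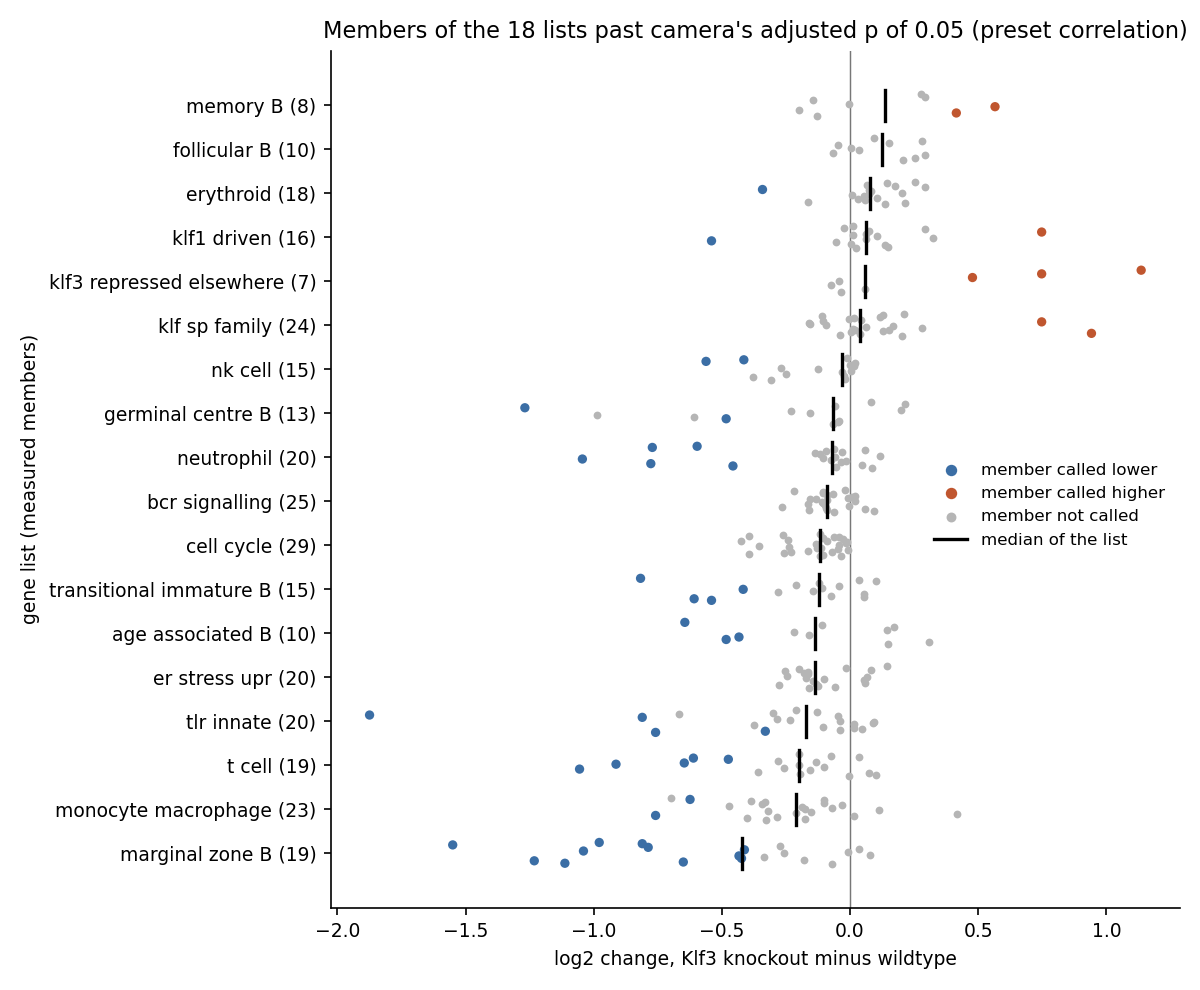
Each point is a member of 1 of the 18 gene lists past a camera adjusted p of 0.05 with the preset correlation, placed by its log2 change (Klf3 knockout minus wildtype); black bars are list medians, and the number of measured members is in parentheses. The marginal zone list has the lowest median (−0.42) with 11 of 19 members called lower (blue), and the T cell, neutrophil and monocyte lists have called members on the lower side too.

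Of 39 lists tested, 18 passed camera with its preset correlation, 6 upward and 12 downward, none passed with a correlation estimated for each list, and the directional fry test called 5 (2 upward, 3 downward) and the mixed fry test 25. The 18 became 11 without the wildtype arrays with high Xist, where besides the follicular and memory B lists those of KLF and SP genes (camera adjusted p = 0.0654, median 0.05), Klf1-driven genes (0.145, 0.06), erythroid (0.102, 0.08), natural killer (0.186, −0.01) and neutrophil markers (0.0654, 0.02 with a downward direction) lost their calls. With the Xist, T cell and monocyte covariates 10, 8 and 11 lists passed, of which 9, 6 and 8 were among the 18. List means, compared by exact permutation of the arrays without adjustment over lists, did not separate all of the 18. The two-sided exact p was 0.143 for the monocyte list. It was 0.0571 for the follicular, age-associated, cell cycle, unfolded protein response, erythroid and Klf1-driven lists. The rest of the 18 gave 0.0286, the smallest possible.

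The other lists did not pass camera. The plasma cell list (18 measured) had Jchain called higher and Mzb1 called lower, 3 higher (Txndc5 and Tnfrsf17 too, 0.50 and 0.33) and 1 lower when adjusted over the list alone, a median of −0.02, a mean of 0.05 and an upward direction (adjusted p = 0.660). The call of Mzb1 was lost without wildtype replicate 1 (−0.39 ± 0.09, limma adjusted p = 0.0829), without knockout replicate 2 and without the wildtype arrays with high Xist (−0.43 ± 0.10, 0.143). Itgb7 and Itga6 (0.43) rose among 24 integrin and adhesion genes (adjusted p = 0.487), with the same 2 higher and 3 lower (Vcam1, Itgal and Itgax, −0.70, −0.26 and −0.22) when adjusted over the list alone. Neither was called without wildtype replicate 1 (Itga6 0.46 ± 0.10, limma adjusted p = 0.0819), without knockout replicate 2 or without the wildtype arrays with high Xist (Itga6 0.44 ± 0.12, 0.256). Among 20 chemokine and lipid receptors Cxcr4 (0.63) and Ccr6 rose and S1pr3, Cxcr2, Ackr3 (−0.70) and Ccr1 fell, with 3 higher (Ccr7 too) and 5 lower (S1pr1 too) when adjusted over the list alone (adjusted p = 0.493). In the Notch list (25) the glycosyltransferase Lfng rose (0.49), in the activation list (24) Cd80 and Cd69 (0.53) rose, and in the complement and Fc receptor list (15) Cr2 and Fcrl5 fell (camera adjusted p of 0.909, 0.528 and 0.217). Adjusted over the list alone, these 3 lists had 1, 2 and 0 members higher and 1 (Dtx1), 2 (Atf3 and Ier3, −0.31 and −0.22) and 2 lower; median and mean differed in sign in each of them, the camera direction being downward. When the wildtype arrays with high Xist were left out, 2 chemokine and lipid receptors, 1 activation gene and no Notch or complement and Fc receptor gene were called. Of the genes that lost their calls with fewer arrays, Ccr6 (0.44) and Ccr1 (−0.60) did not shrink. Cxcr4 (0.58), Lfng (0.42), Cd69 (0.44), Cr2 (−0.37), Fcrl5 (−0.32) and Ackr3 (−0.48) changed less than with all arrays.

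No member was called over all genes in the lists of B cell identity (17 measured, camera adjusted p = 0.363), BAFF and NF-kB signalling (21, 0.188), interferon response (23, 0.304), class II antigen presentation (10, 0.487), cholesterol and lipid synthesis (19, 0.217) and metabolic genes tied to Klf3 in fat (9, 0.909). The same held for markers of dendritic cells (14, 0.659), platelets (11, 0.194), mast cells and related granulocytes (13, 0.717) and stroma (19, 0.799), and for ribosomal (21, 0.174), heat shock (9, 0.830) and housekeeping genes (10, 0.830). Adjusted over the list alone, 3 BAFF and NF-kB genes were higher (Nfkbia 0.23, Bcl2 0.24, Tnfrsf17 0.33), 1 mast cell marker was lower (Hdc, −0.49), and none changed in the others. The sex-linked list (4 measured) and the immunoglobulin list (3 measured: Igha 0.42, Ighg3 0.36 and Ighm 0.26, none called over all genes, all 3 higher when adjusted over the list alone) were too small for camera. So adjusted, all 4 sex-linked genes differed, with Xist lower in the knockout-labelled arrays and Eif2s3y, Uty and Kdm5d higher. Without the wildtype arrays with high Xist the changes of Xist, Eif2s3y, Uty and Kdm5d were 0.07, −0.07, −0.11 and −0.16.

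Tlr6 lies beside Klf3, with only Tlr1 between them among the measured genes. A targeted allele can carry flanking DNA of another strain, so genes within 20 Mb of Klf3 were compared with all others. Of 136 such genes 2 were called (1.47%, against 1.25% elsewhere), a difference that did not pass (odds ratio 1.18, Fisher's exact p = 0.689, two-sided). The 2 were Tlr6 and its next neighbour Fam114a1, which rose by 0.45 ± 0.07 (limma adjusted p = 0.0102; 0.43 ± 0.09 and 0.0668 without the wildtype arrays with high Xist), whereas Tlr1 changed by −0.04 ± 0.07 and was not called.

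**Figure D4:**
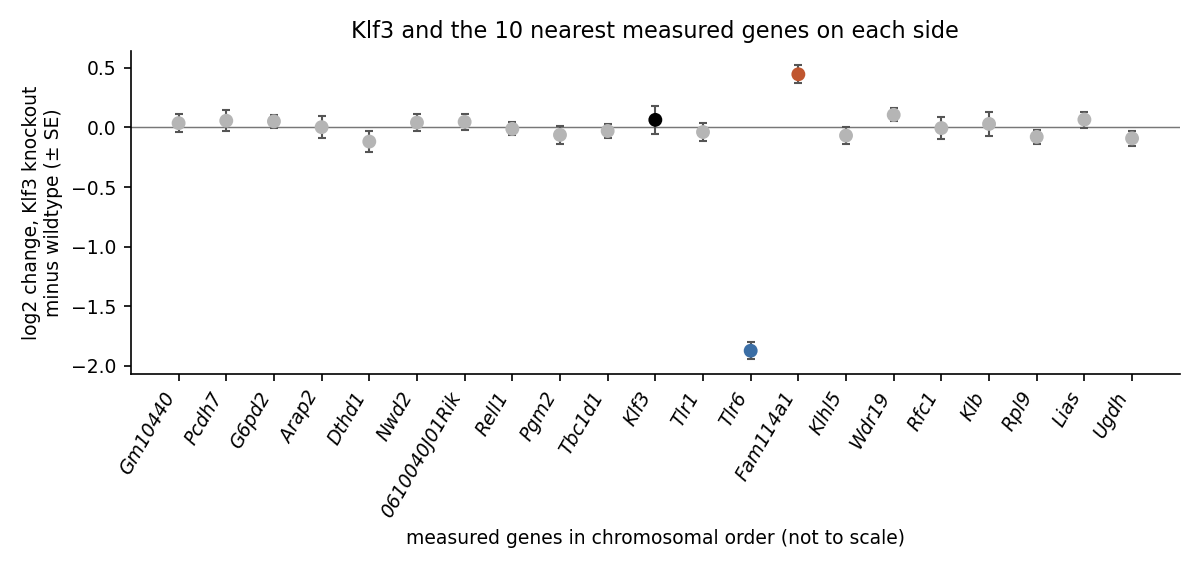
Points are the log2 changes (Klf3 knockout minus wildtype) of Klf3 and the 10 nearest measured genes on each side in chromosomal order, not to scale, with bars for the SE from limma. Tlr6 at −1.87 (blue) and Fam114a1 at 0.45 (orange) are the called genes, and Klf3 (black) is at 0.06.

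Within a genotype, 1 array stood apart from the other 3 for several genes named here. This was about as frequent as chance gives, with 26 of 474 groups of 4 arrays, list means included, against 23.7. Wildtype replicate 1 was highest for Jchain, Cd36, Zc3h12c and S100a8, wildtype replicate 3 lowest for Ccl3, Il1b and Csf3r, and knockout replicates 2, 3 and 4 stood apart for Cd14, Slc25a37 and S100a9.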

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

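The tests chosen after the result was seen are those on the marginal zone list, on Tlr6 and on the markers of other cell types; leaving out wildtype replicate 1 and the count over splits of the arrays were planned, the former without bounds for these lists.

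Across the 35 splits of the 8 arrays into 4 and 4, 1 split, the real one, gave as many as 250 genes, and the highest of the others gave 0. That is the smallest share 35 splits can give, and every other split mixes the genotypes, which adds any difference between them to the spread. By unadjusted limma p under 0.05, splits that mixed the genotypes gave 2564, 2089, 2071 and 2003 genes, against 1933 in the real one. Chance as the source of the gene count is therefore not excluded. For the lists, 1 of the 35 splits, again the real one, gave as many as 18, but the highest of the others gave 17. That split exchanged wildtype replicate 2 for knockout replicate 1 and so kept 3 arrays of each genotype, and both arrays with high Xist, together; splits with 2 arrays of each genotype on each side gave at most 10 lists. Splits balanced for genotype thus also called lists at the preset correlation, and with an estimated correlation 0 of 39 passed in the real split. Chance as the source of the list count is therefore not excluded.

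The fall of the marginal zone B list (11 of 19 members called, median −0.42) had 3 explanations to weigh besides the genotype, which stays a hypothesis. Without the wildtype arrays with high Xist the median was −0.370, and 6 members and not 11 were called with fewer arrays. The list means of wildtype replicates 2 and 4 (9.119 and 9.182) lay above those of the knockout-labelled arrays (8.615 to 8.777). The size of the fall thus argues against unequal sex as the whole cause. The camera adjusted p there (2.90e-21) takes the members as nearly independent, at the preset correlation of 0.01. With the estimated correlation of 0.26, all 8 arrays gave 0.0578, and the smaller fit was not tested that way. Without wildtype replicate 1, which had the highest list mean (9.42), the median was −0.386 with 10 members called, which argues against that array alone. A smaller share of marginal zone B cells among the sorted cells may account for the fall as well as a lower level per cell. The members' changes had an SD of 0.471 around their mean, and bulk arrays cannot part a share from a level, so these cannot be told apart.

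Tlr6 fell by 1.87 ± 0.07 on the log2 scale, and it lies close to Klf3. With the mean of the marginal zone list as a covariate its change was −2.26 ± 0.206 (limma adjusted p = 0.00265). That mean had 89.9% of its variance between the genotypes, so little of it was left to adjust with. A smaller share of marginal zone B cells therefore stays open as a cause. The covariate left 2 genes called, Tlr6 and Cnr1. An effect of the targeted allele, or of DNA of another strain carried beside it, may also lower Tlr6 without Klf3 protein being involved, by its regulation or by a probe mismatch. Among the 19 other nearest measured genes 1 was called, Fam114a1 (Fisher's exact p = 0.213, two-sided, odds ratio 4.40 with a 95% interval of 0.105 to 28.1). Too few neighbours were called to decide, so an effect of the allele and an effect of losing the factor cannot be told apart for Tlr6.

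The fall of T cell, neutrophil, monocyte and natural killer cell markers (14 called members) may reflect fewer cells of other types left after bead selection for CD19, which should remove them. If all other cells were fewer, erythroid, dendritic and stromal markers would fall alike. Among members above the median gene, the largest gap between their medians and that of the monocyte list was 1.75 of the members' combined SD. The gaps of the natural killer and neutrophil lists were 3.18 and 1.36 (3 members each), and that of the T cell list was 0.685. These gaps cannot decide, since a marker above the median gene may come from the B cells themselves and would then not fall. A loss of all other types and a selective loss both stay open. The brightest members of the 4 lists in wildtype were Cd2 (11.2, change 0.10), Vcam1 (9.45, −0.70), Ccl5 (7.82, −0.31) and S100a9 (7.27, −0.60), and 11 of 19, 15 of 23, 3 of 15 and 3 of 20 members of the T cell, monocyte, natural killer and neutrophil lists lay above the median gene; 2, 3, 0 and 1 stand in another list. Without wildtype replicate 1, which had the highest means of all 4 lists, 7 members were still called. Of these 4 were T cell markers, against 5 with all arrays, which argues against that array alone for the T cell list. The neutrophil, monocyte and natural killer lists kept 1 each, against 5, 2 and 2, too few to decide for them. Over the 4 lists, 4 members were called without knockout replicate 2 and 6 without the wildtype arrays with high Xist. In the latter 2 fits, in that order, the monocyte median was −0.28 and −0.15, against −0.21 with all arrays. The T cell median was −0.16 and −0.12, against −0.20. The genotype, the sex of the mice and the purity of the sorts remain open.

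In 26 of 474 groups of 4 arrays, 1 array stood far from the other 3 by Dixon's ratio of gap to range; chance gives about 1 in 20, here 23.7. Wildtype replicate 1 was the far array in 8 of them, the most of any array, and lay highest for Jchain (11.5 against 11.0 for the others, ratio 0.920), Cd36 (10.3 against 9.76 to 9.80, 0.924), Zc3h12c (9.70 against 9.20 to 9.27, 0.854), Pou2af1 (11.6 against 11.4, 0.841), S100a8 (7.11 against 6.58 to 6.66, 0.839), Sema7a (9.74 against 9.26 to 9.27, 0.970) and the means of the age-associated B list (7.52 against 7.36 to 7.39, 0.850) and the neutrophil list (6.31 against 6.04 to 6.08, 0.845). Wildtype replicate 3 lay lowest for Ccl3 (6.55 against 7.90 to 8.16, 0.841), Atf3 (6.64 against 6.78 to 6.80, 0.850), Il1b (6.32 against 7.32 to 7.50, 0.847) and Csf3r (6.15 against 6.55 to 6.56, 0.975). Wildtype replicate 2 lay highest for Scd1 (0.837), and wildtype replicate 4 for Syvn1 (0.910) and the means of the B cell identity list (0.888) and the CtBP list (0.893). Knockout replicate 4 lay lowest for Itgax (0.913), Bub1b (0.919) and S100a9 (0.839) and highest for Adam10 (0.862) and the T cell list mean (0.906). Knockout replicate 2 lay highest for Cd14 (0.866) and the mean of the cholesterol list (0.865), and knockout replicate 3 lowest for Slc25a37 (0.834), Clec4n (0.868) and Cd27 (0.850).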

How the results depend on the processing

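The tests added after the result was seen are those without the wildtype arrays with high Xist. Against the 250 genes of the main test, 92 were called with an Xist covariate (85 shared), 10 with the T cell covariate (10 shared), 20 with the erythroid covariate (19 shared), 97 with the monocyte covariate (84 shared) and 93 without the wildtype arrays with high Xist (85 shared). Of the 250, 94 passed with a fold of at least 1.5. Of all genes, 1168 had genotypes that did not overlap. Leaving out 1 array gave 148 (wildtype replicate 1) to 248 (knockout replicate 3) genes, and 163 without knockout replicate 2. Against 18 of the 39 lists, 11 passed with probe sets at or above the median probe set (10 shared), 10 with the Xist (9 shared), 8 with the T cell (6 shared) and 11 with the monocyte covariate (8 shared), 11 without the wildtype arrays with high Xist (11 shared), 5 with directional fry (5 shared), 0 with camera and an estimated correlation, and 14 to 19 with 1 array left out. Fewer arrays, or a covariate that shares variance with the genotype (32.3% for Xist, 58.4% for the T cell, 50.7% for the erythroid and 37.8% for the monocyte mean), leave less power; beyond that the cause was not tested. List directions turned for germinal centre genes with the filter at the median probe set (adjusted p = 0.6645), natural killer genes with the T cell covariate (0.6585) and monocyte genes with their own covariate (0.7476); the causes were not tested apart from the last, which removes the list's own mean. The exact p of the separation by genotype was 0.0667 without the wildtype arrays with high Xist, the smallest that 2 against 4 can give, and 0.0286 to 0.343 with 1 array left out (0.343 without wildtype replicate 1, 0.0571 without knockout replicate 1 or 2). Quantile normalization again, centring, a log2 mean of at least 6, other probe sets per gene, array weights, trend with robust, an adjusted p of 0.1 and leaving out genes near Klf3 kept gene counts within 1.5 times. With the replicate number as a block 262 genes were called (222 shared) and 16 lists. Numbers did not pair the arrays, since 1 of 4 wildtype arrays resembled the knockout array of its own number best. Klf3 changed by −0.02 to 0.20 over all alternatives (lowest adjusted p = 0.290). The array's lowest signals lie near 2.25, and dim genes are limited by background.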

Other observations

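The annexin, S100a, galectin and Clec4 families and the 2 families described after them were picked after the largest changes were seen; the tests on the 4 former were set before their own results were seen, and the genes named here were chosen after their values were seen.

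Annexins, calcium-dependent membrane-binding proteins, were higher in the knockout-labelled arrays beyond Anxa2. Of 11 other measured members Anxa1 (0.48 ± 0.10) and Anxa5 (0.43 ± 0.07) rose and none fell, with a median log2 change of 0.228 (camera adjusted p = 2.97e-07; adjusted p = 0.00530 with an estimated correlation). Without the wildtype arrays with high Xist the changes of Anxa1 (0.52 ± 0.12, limma adjusted p = 0.143) and Anxa5 (0.45 ± 0.10, 0.0870) were no smaller but, with fewer arrays, not called. A rise of the family as a group is a hypothesis that passed this test. The same hypothesis did not pass for the S100a family besides S100a6 and S100a8 (11 members, median −0.0321, camera adjusted p = 0.541, S100a9 called lower), for the galectins besides Lgals1 and Lgals3 (6 members, median −0.00801, 0.784) or, as a fall, for the Clec4 lectins besides Clec4d and Clec4e (9 members, median 0.00589, 0.393). The camera direction of the Clec4 members was downward against a median above 0, and Clec4n alone among them was called (−1.03).

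Regulators of G-protein signalling and semaphorins with their receptors had called members on the lower side. Among 20 measured Rgs genes 4 fell, Rgs13 (−1.27), Rgs2 (−0.80), Rgs18 (−0.71) and Rgs1 (−0.45), with a family median of 0.02. Among 31 semaphorin, plexin and neuropilin genes 5 fell, Sema7a (−1.04), Sema5a (−0.72), Plxnc1 (−0.44), Nrp2 (−0.39) and Sema4b (−0.38), and none rose. The median of the 31 was −1.5e-05. Without the wildtype arrays with high Xist Rgs2 (−0.89), Rgs1 (−0.50) and Sema7a (−0.93) stayed called, so 2 of 4 and 1 of 5. Without wildtype replicate 1, 2 of 4 and 3 of 5 stayed called, Rgs1 (−0.39, limma adjusted p = 0.139), Rgs18 (−0.64, 0.1001), Plxnc1 (−0.40, 0.0516) and Nrp2 (−0.35, 0.0700) being lost. These families were not tested as groups. Cnr1, a cannabinoid receptor gene, rose by 0.72 ± 0.10 (limma adjusted p = 0.00298), and by 1.59 ± 0.184 with the mean of the marginal zone list as a covariate (limma adjusted p = 0.017), where that mean had 89.9% of its variance between the genotypes.

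Tested on their own, 250 of 28901 probe sets were called, of which 195 stood for their gene, 14 were other single-gene probe sets, 18 carried several genes and 23 carried no gene in the annotation.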
